A study of Danio rerio with 4 samples.

How the data were processed

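Messenger RNA was measured by sequencing in the whole gut of 4 adult zebrafish (Danio rerio). Per the labels, 2 fish were heterozygous and 2 homozygous for a mutation of irf8 (allele st95), and the design text describes them as separate animals. RNA was extracted with a column kit for small samples, messenger RNA was captured on oligo-dT beads, and strand-specific libraries were amplified by PCR, per the labels' protocols. The labels give no batch, and all 4 libraries carry the same lane code.

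The deposited count table holds whole-number counts of read pairs per gene. Per the file headers, the authors made these counts with featureCounts from Subread 1.5.2, summed over the exons of each gene, with paired reads and reverse strand (setting 2), on the UCSC gene annotation of the genome build danRer10. The submitters' processing notes also name DESeq2 and R 3.3.1. The aligner is not given in the sources used here. Reads shared by near-identical gene copies, such as globins, trypsins, chitinases and MHC genes, can be lost or split in such counts, so the values of single members of those families are uncertain. Because counting used the strand, antisense genes were kept apart.

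A second deposited table lists 76 genes with a log2 fold change, a p-value with FDR and Bonferroni corrections, and a maximum group mean whose unit and groups the file does not name. The authors' log2 fold changes, and the FDR values among these deposited p-values, were compared with the values computed here. The deposited maximum group mean, a score without a stated unit, was not tested. Of its 76 genes, 41 matched a gene of the count table by name and 35 did not. The table gives 30 genes a positive and 46 a negative fold change, and its highest FDR is 0.0537.

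The count table holds 14781 genes. Total counts per library were 6350840 and 10391963 in heterozygotes and 6389553 and 9351100 in homozygotes (replicates 1 and 2 of each). A count of 0 allows up to 3 counts, which is 0.512, 0.328, 0.444 and 0.277 CPM (counts normalised to library size) in the same order. Shares of counts are given with exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only, since PCR copies were not told apart by molecular identifiers.

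Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 9701 genes, and libraries were scaled by TMM. Homozygous mutants were compared with heterozygotes by edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. Standard errors of log2 fold changes are those implied by the F statistic. CPM values are TMM-normalised, and mean ± SD is over the 2 libraries of a group. For a gene at 0 in both libraries of a group, the fold is a lower bound against 3 counts per library; for a gene with 1 to 3 counts in a group, it is the ratio of summed counts with its counting interval.

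The design, the alternatives, 23 gene lists and the rule for named genes were fixed before the data were examined. Of 842 list members, 576 were found by name and 45 by synonym, 11 repeated another member of their list, and 210 were not found. The synonym table belongs to the assembly GRCz12tu and was used for names only. Coordinates are those of the count table. Lists with at least 3 tested members were compared with all other genes by limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. The same lists were run with an estimated correlation and with fry, which tests whether a set moves on balance in one direction. With an estimated correlation camera draws its degrees of freedom from the libraries, and with the preset from the genes. P-values were adjusted over the 21 lists tested. The gonad list had 0 tested members, and the list of mitochondrially encoded genes had 0 members in the table.

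Named genes are irf8, the 3 C1q genes, up to 10 called genes per direction with non-overlapping libraries and a mean of at least 1 CPM, up to 4 members of each list with the smallest unadjusted p, and the 5 higher and 5 lower genes of the deposited 76-gene table with the smallest adjusted p here. Ties in adjusted p were broken by the unadjusted p. The part of the rule for called genes gave 0 genes. A feature named outside this rule is identified as chosen after its values were seen.

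The alternatives tried were DESeq2's size factors in place of TMM, no count filter beyond 1 count in any library, a mean of at least 1 CPM, DESeq2's Wald test (DESeq2 1.42.0), the replicate number as a block, each library left out in turn, the pancreas and liver lists left out, an adjusted p of 0.1, and a fold threshold of 1.5. The older form of the quasi-likelihood fit was also to be tried, but it is the default of the installed edgeR and so coincides with the fit reported; the newer form was added after the data were seen. DESeq2 counts without each library, with the block and without pancreas and liver genes were added at the same time. With a library left out the count filter was run again, so list values there can cover other members than with all libraries.

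The procedure was tested on counts simulated for the same 9701 genes and library sizes, with 200 genes changed by known folds. At the dispersion estimated from these libraries, edgeR recovered 0% of genes changed 2-fold, 20% changed 4-fold and 63.9% changed 8-fold, with 5 false calls. DESeq2 recovered 1.27%, 30% and 65.6%, with 14 false calls. The simulated dispersion was edgeR's trend over abundance, without further spread between genes. No simulated library was set apart from the others as heterozygous replicate 2 is. The recovered shares may therefore exceed what these libraries allow. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.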

Results

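Whole-gut messenger RNA was sequenced from 2 adult zebrafish heterozygous and 2 homozygous for the st95 allele of irf8, a gene for a transcription factor required for macrophage development. Library totals ranged from 6350840 to 10391963 counts, and 11059 to 12486 genes had at least 1 count. Log2 CPM correlated across genes at r = 0.852 between the heterozygous libraries, 0.912 between the homozygous libraries, and 0.849 to 0.911 between genotypes; genes are not independent replicates.

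The comparison of homozygous with heterozygous fish asks which gut transcripts differ when irf8 function is lost. The 3 C1q genes, which encode the chains of the complement component that starts the classical pathway and are made by tissue macrophages, were lower in both homozygous libraries than in either heterozygous library. Genes of mononuclear phagocytes went both ways: ccl34b.1, a chemokine gene, havcr1, a phosphatidylserine receptor gene, and csf1ra, the gene for a receptor of the macrophage growth factor CSF1, were among 8 with both homozygous libraries lowest, and 7 had both highest. Genes of T and NK lymphocytes, interferon response, antigen presentation and enterocytes were higher as lists. With an estimated correlation these 4 calls were lost (camera adjusted p = 0.732, 0.545, 0.545 and 0.732). The estimate was 0.834 for T and NK and 0.440 for enterocyte genes. For interferon and antigen presentation genes it was 0.00988 and -0.000877, no higher than the preset 0.01, so correlation did not end those calls. Without heterozygous replicate 2 the calls of antigen presentation and enterocytes were lost too. Their mean log2 fold changes stayed near those with all libraries (0.62 against 0.58, and 0.46 against 0.53). Pancreas and stromal genes were lower, but on average neither list was lower without heterozygous replicate 2. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 of 9701 genes were called and the lowest adjusted p was 0.699, so single genes are given below by their values.

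The targeted gene, irf8 (chromosome 18, 30589736 to 30595588, plus strand, 8 exons in danRer10), had 30 and 50 counts in the heterozygous and 25 and 25 in the homozygous libraries. That is 5.12 and 5.47 CPM (counts normalised to library size) against 3.70 and 2.31, a log2 fold change of -0.82 ± 0.58 (SE) with an edgeR adjusted p of 0.729. The transcript level does not by itself check the genotype labels, since an allele need not remove the transcript.

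The C1q genes lie together on chromosome 21, on the minus strand, with c1qb at 22675702 to 22678651 (3 exons), c1qc at 22681221 to 22683754 (2 exons) and c1qa at 22685353 to 22688313 (3 exons). c1qc averaged 5.77 ± 1.89 CPM (mean ± SD, n = 2) in heterozygotes and 0.333 ± 0.0516 in homozygotes, 16.5-fold lower (log2 fold change -4.04 ± 0.76, SE). c1qb averaged 5.27 ± 3.84 and 0.693 ± 0.0668 CPM, 7.55-fold lower (-2.92 ± 0.86). c1qa had 12 and 41 counts in heterozygotes and 0 and 1 in homozygotes, a ratio of 62.2 with a 95% counting interval of 10.7 to 2501. As a list the 3 genes fell (camera adjusted p = 1.13e-05), with 0 called over all genes and 3 adjusted over the list alone. The list's adjusted p = 0.545 with an estimated correlation. DESeq2 called c1qc (adjusted p = 0.0417; range over the alternatives 0.0417 to 0.999), and without heterozygous replicate 2 too few C1q genes passed the count filter for a list test.

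Of 24 tested mononuclear phagocyte genes, 13 were lower and 11 higher, and the list was not called (camera adjusted p = 0.266). ccl34b.1 had 17 and 16 counts in heterozygotes and 0 in both homozygous libraries, at least 6.45-fold lower. havcr1 had 12 and 21 counts against 0 and 2, a ratio of 19.4 with a counting interval of 4.95 to 166. csf1ra averaged 1.62 ± 0.124 CPM in heterozygotes and 0.212 ± 0.0910 in homozygotes. grn2, a granulin gene, was more abundant, at 126 ± 2.63 CPM against 56.8 ± 5.55, 2.23-fold lower (-1.15 ± 0.37, SE). These 4 genes have the smallest unadjusted p of the list, and all are lower. Among members named after their values were seen, mfap4 was at 0.28 ± 0.50 and mpeg1.1 at -0.58 ± 0.47. Higher members included lgals9l1 (0.88 ± 0.42) and slco2b1 (0.89 ± 0.43). The list's libraries did not overlap for 8 lower and 7 higher members, where 39.2% of all tested genes did not overlap and chance gives 33.3%.

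**Figure D1:**
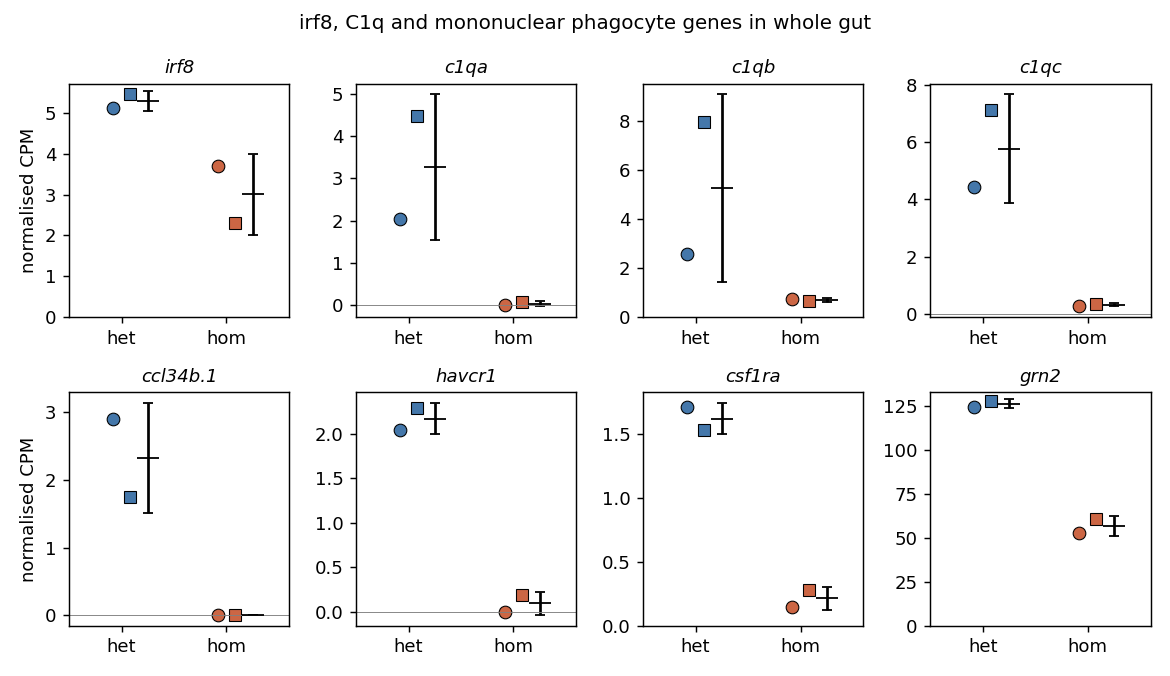
Normalised CPM (y axis, linear, a separate scale per gene) of irf8, the C1q genes and 4 mononuclear phagocyte genes in heterozygous (het, blue) and homozygous (hom, orange) libraries. Circles are replicate 1, squares replicate 2, and black bars the mean ± SD (n = 2). In all 8 genes both homozygous libraries lie below both heterozygous ones. The 4 phagocyte genes are those with the smallest unadjusted p among 24 tested, of which 11 were higher.

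Genes of T and NK lymphocytes rose as a list (camera adjusted p = 1.65e-07), with 17 of 18 tested members higher and a median log2 fold change of 1.95. This list's adjusted p = 0.732 with an estimated correlation. runx3, a transcription factor gene of cytotoxic lymphocytes, averaged 6.71 ± 1.04 CPM in heterozygotes and 32.3 ± 3.94 in homozygotes, 4.80-fold higher (2.26 ± 0.37, SE), and was called by DESeq2; it was the 1 member called adjusted over the list alone, against 0 over all genes. foxp3a, the regulatory T cell factor, had 0 and 6 counts in heterozygotes and 96 and 20 in homozygotes, and itk, a T cell kinase gene, reached 32.1 CPM in homozygous replicate 1 and 6.27 in replicate 2. The T and NK list took 0.0403% of counts in homozygous replicate 1 (interval 0.0388 to 0.0419) and 0.0187% in replicate 2 (0.0178 to 0.0196), against 0.00572% and 0.0101% in the heterozygotes. With the preset correlation of 0.01 the call held without each library in turn, but the correlation estimated for this list was 0.834. The same setting called the liver list in opposite directions with different libraries left out, so a call that holds is weak evidence. The T and NK median ranged from 1.08 without homozygous replicate 1 to 2.70 without heterozygous replicate 2. Only 3 B lymphocyte genes were tested and the list was not called (camera adjusted p = 0.10), except in 2 alternatives. These were the replicate number as a block (0.0472) and heterozygous replicate 2 left out. The latter tested 6 B lymphocyte genes, with a mean log2 fold change of 3.53, against 0.97 over the 3 with all libraries. blnk, a B cell adaptor gene, averaged 2.25 ± 1.17 and 9.30 ± 0.882 CPM and was the 1 B lymphocyte gene called adjusted over the list alone, against 0 over all genes.

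Interferon response genes rose as a list, with 17 of 18 tested members higher (camera adjusted p = 4.45e-05; adjusted p = 0.545 with an estimated correlation). irf1b, an interferon regulatory factor gene, was at 13.1 and 19.8 CPM in heterozygotes and 126 and 74.4 in homozygotes, 6.05-fold higher (2.60 ± 0.46, SE). It was the 1 member called adjusted over the list alone, against 0 over all genes, and it was called by DESeq2. Antigen presentation genes rose too, with 12 of 18 higher (camera adjusted p = 0.0068; adjusted p = 0.545 with an estimated correlation). Among them the MHC class I region genes abcb3l1 (4.42-fold, 2.14 ± 0.48), mhc1uba (4.12-fold, 2.04 ± 0.52) and tapbp (3.33-fold, 1.74 ± 0.49) are neighbours on chromosome 19. The costimulatory receptor gene cd40 was 4.83-fold higher (2.27 ± 0.58). The 6 lower members included ifi30 (-1.98 ± 0.69), ctsl.1 (-1.44 ± 0.84) and cd74a (-0.81 ± 0.68), named after their values were seen. Without heterozygous replicate 2 the antigen presentation call ended at an adjusted p of 0.135 (mean log2 fold change 0.62, against 0.58 with all libraries), and without homozygous replicate 1 at 0.115 (0.44), within a range over the alternatives of 0.00155 to 0.545.

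Inflammatory cytokine and mediator genes rose as a list, with 10 of 16 higher (camera adjusted p = 0.0260; adjusted p = 0.732 with an estimated correlation). ccl19b, a lymphocyte-attracting chemokine gene, averaged 24.6 ± 1.67 CPM in heterozygotes and 168 ± 109 in homozygotes, 6.82-fold higher (2.77 ± 0.59, SE), and was called by DESeq2. tnfb and il1b, genes of inflammatory cytokines, stayed under 3 CPM in homozygotes, with 16 and 16 and with 19 and 24 counts. Neutrophil genes rose as a list, with 13 of 18 higher (camera adjusted p = 0.0460; adjusted p = 0.682 with an estimated correlation). cybb, the gene for the oxidase subunit of phagocytes, was 2.40-fold higher (1.26 ± 0.54) and the interleukin 6 receptor gene il6r 3.62-fold (1.86 ± 0.72). With each library left out in turn, the il6r value ranged from 0.98 to 2.42 and the cybb value from 1.05 to 1.47. The neutrophil list took 0.0640% and 0.0386% of counts in the heterozygotes and 0.0560% and 0.0660% in the homozygotes. Only heterozygous replicate 2 was low by this summed share, which the most abundant members dominate. For cybb and il6r heterozygous replicate 1 was the lowest library, at 2.56 and 1.54 CPM, against 3.39 and 2.19 in heterozygous replicate 2. Without homozygous replicate 1 neither list was called. The inflammatory mean log2 fold change was then -0.47 over 19 members and the neutrophil one 0.28 over 19. With all libraries they were 0.68 over 16 and 0.56 over 18. The inflammatory value was -0.16 over 21 members without heterozygous replicate 1, where the list was not called. Neutrophil genes reached 1.26 over 19 members without heterozygous replicate 2, where their call was lost as well.

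In the same libraries, genes of tissue handling and stress rose as a list, with 26 of 37 higher (camera adjusted p = 0.00312; adjusted p = 0.732 with an estimated correlation). The immediate-early transcription factor genes jund (4.48-fold, 2.16 ± 0.49, SE), junbb (3.84-fold, 1.94 ± 0.49) and egr1 (5.61-fold, 2.49 ± 0.66) were higher in both homozygous libraries, as was the heat shock cofactor gene dnajb1b (2.85-fold, 1.51 ± 0.39). In 19 members both homozygous libraries were highest and in 6 both were lowest. DESeq2 called 3 members higher and 1 lower. Among the 11 lower members, named after their values were seen, were hspa5 (-1.87 ± 0.53, the DESeq2 call), klf2a (-2.71 ± 0.79) and hmox1a (-2.46 ± 0.86). The stress call ended without heterozygous replicate 2 (adjusted p = 0.177, mean log2 fold change 0.59 against 0.44 with all libraries) and without homozygous replicate 1 (0.498, mean -0.09, median 0.29), within a range over the alternatives of 0.000337 to 0.732. Of 11 antimicrobial genes 6 were higher and 5 lower (camera adjusted p = 0.724). In that list the test was positive and the mean log2 fold change was -0.39, and only without homozygous replicate 2 was it called (0.0453; range 0.0453 to 0.943). intl2, an intelectin gene, was 3.36-fold higher (1.75 ± 0.57), and tlr5b, a flagellin receptor gene, 4.99-fold lower (-2.32 ± 0.82). Of 4 eosinophil and mast cell genes 2 were higher and 2 lower (camera adjusted p = 0.364). Their mean log2 fold change of -0.94 went to 2.07 without heterozygous replicate 2 and to -2.94 without homozygous replicate 2. The direction of the test did not reverse. With all libraries the largest change was that of cpa5 (-3.39 ± 1.65). It was at 814 and 11647 CPM in heterozygotes and 1070 and 116 in homozygotes. Its libraries ranked as they did for the share of pancreas genes, so its value need not reflect mast cells. rnasel2 had 0 counts in replicate 1 of both genotypes, and its value ranged from -7.95 to 8.36 without 1 library.

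**Figure D2:**
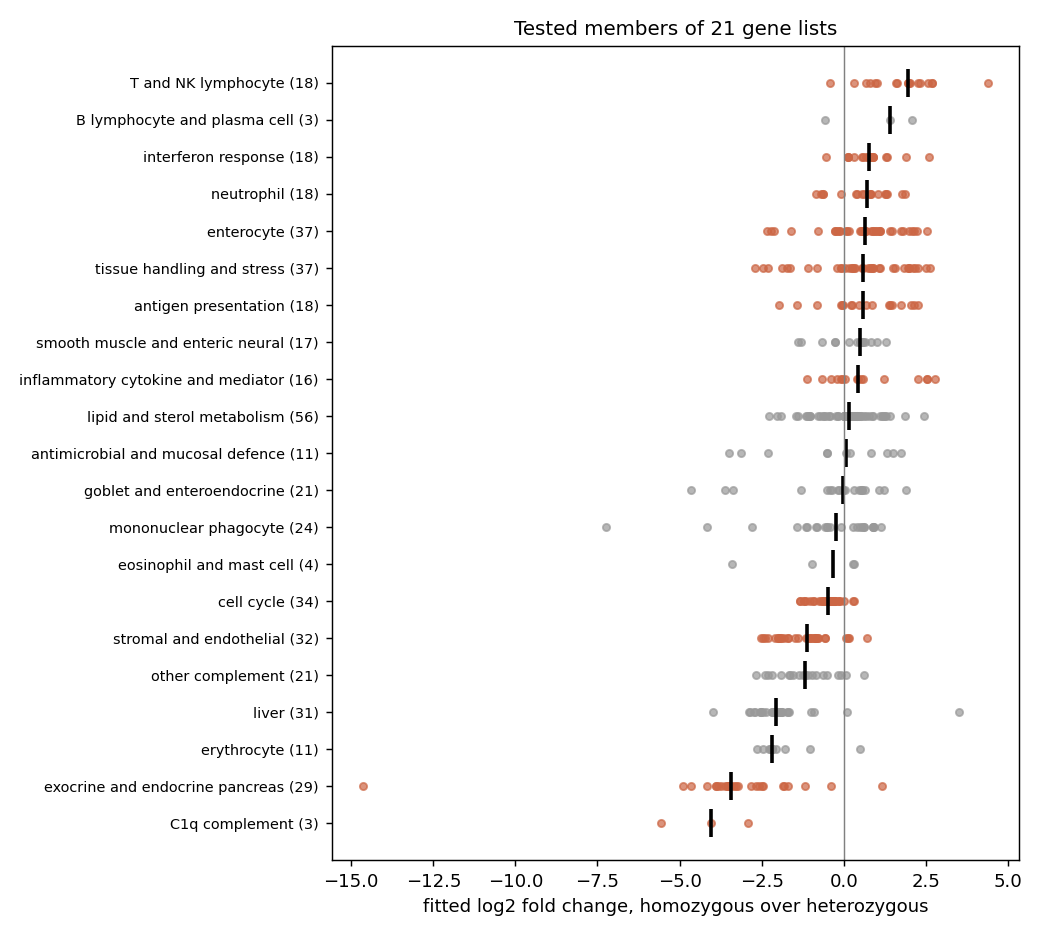
Fitted log2 fold changes (x axis, homozygous over heterozygous) of the tested members of 21 gene lists (y axis, number of tested members in brackets). Each point is a gene and each black bar the list's median; orange lists passed the camera test with the preset correlation and 0 lists passed with an estimated one. The leftmost point is ins, whose fitted value is not a bound because both homozygous libraries are at 0.

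Enterocyte genes rose as a list, with 27 of 37 higher and 10 lower (camera adjusted p = 4.45e-05; adjusted p = 0.732 with an estimated correlation). slc6a19a.1, the gene for a neutral amino acid transporter of the brush border, averaged 119 ± 0.734 CPM in heterozygotes and 564 ± 58.9 in homozygotes, 4.72-fold higher (2.24 ± 0.46, SE). slc15a1b, the gene for the intestinal peptide transporter, averaged 236 ± 56.1 and 994 ± 360 CPM, 4.22-fold higher (2.08 ± 0.57). mep1b, a brush border peptidase gene, averaged 250 ± 37.7 and 871 ± 98.0 CPM, 3.48-fold higher (1.80 ± 0.50). DESeq2 called all 3, and in all it called 4 higher and 1 lower enterocyte gene. Beside these values, the enterocyte list took 6.17% of the counts of heterozygous replicate 2 (interval 6.16 to 6.19) and 15.8% to 18.7% of the other 3 libraries. Without that library the list's mean log2 fold change was 0.46, against 0.53 with all libraries, and its adjusted p 0.606, within a range over the alternatives of 1.35e-08 to 0.732. Without homozygous replicate 2 the mean was 0.02.

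Hormone genes of the gut and pancreas went both ways, and the goblet and enteroendocrine list was not called (camera adjusted p = 0.988; 10 higher and 11 lower, mean -0.35, median -0.02, direction of the test positive). Of its 21 members 2 were called adjusted over the list alone and 0 over all genes. penka, an enkephalin precursor gene, averaged 11.3 ± 0.0790 and 42.5 ± 6.01 CPM, 3.75-fold higher (1.91 ± 0.34, SE). ghrl, the ghrelin gene, averaged 27.2 ± 22.1 and 2.60 ± 0.112 CPM, 10.5-fold lower (-3.39 ± 0.72). The glucagon genes gcga (12.3-fold, -3.62 ± 0.97) and gcgb (25.4-fold, -4.66 ± 1.26) were lower as well, and both were highest in heterozygous replicate 2, at 228 and 85.2 CPM. Without that library the log2 fold changes were -2.16 for ghrl, -1.57 for gcga and -1.78 for gcgb. DESeq2 called these 4 genes.

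**Figure D3:**
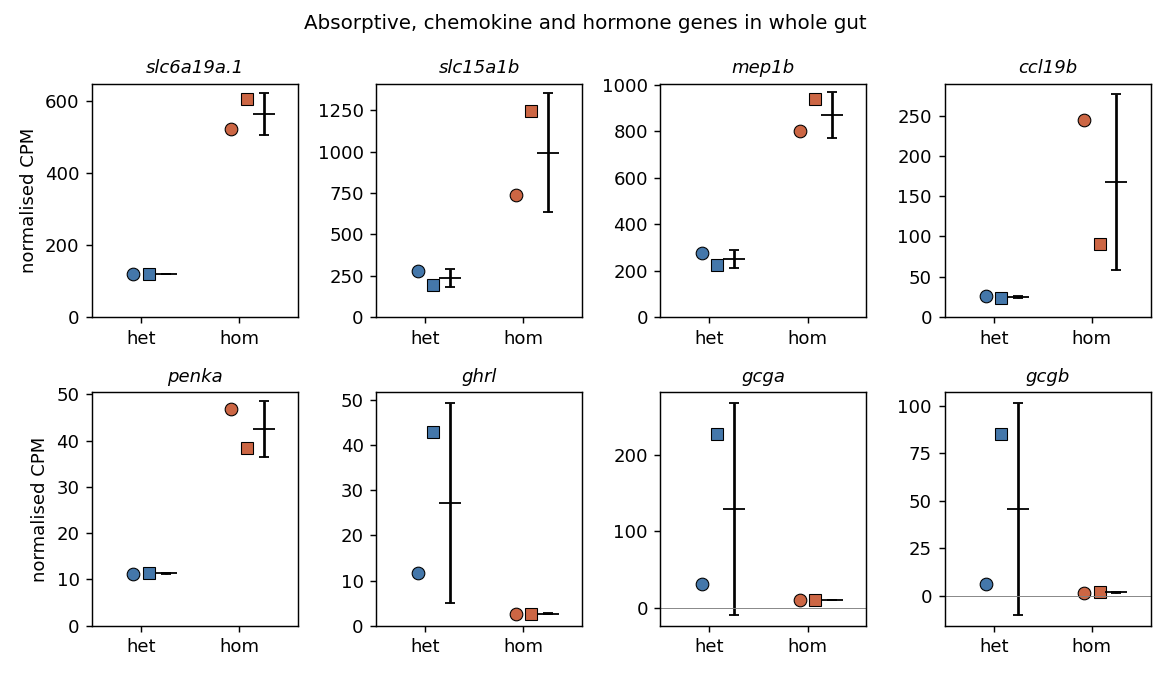
Normalised CPM (y axis, linear, a separate scale per gene) of 3 absorptive genes, the chemokine gene ccl19b and 4 hormone genes in heterozygous (het, blue) and homozygous (hom, orange) libraries. Circles are replicate 1, squares replicate 2, and black bars the mean ± SD (n = 2); ghrl, gcga and gcgb are highest in heterozygous replicate 2.

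Pancreas genes fell as a list, with 28 of 29 lower and a median log2 fold change of -3.43 (camera adjusted p = 2.17e-06; adjusted p = 0.732 with an estimated correlation). The pancreas list took 36.0% of all counts in heterozygous replicate 2 (interval 36.0 to 36.1), against 1.62% (1.61 to 1.63) in heterozygous replicate 1, 4.93% (4.92 to 4.95) in homozygous replicate 1 and 0.532% (0.528 to 0.537) in homozygous replicate 2. Only 3 of the 29 genes had both homozygous libraries below both heterozygous ones. Without heterozygous replicate 2 the list's mean log2 fold change was 0.12 (adjusted p = 0.334), within a range over the alternatives of 5.01e-15 to 0.814. The insulin gene ins (chromosome 5, 37254542 to 37257536, plus strand, 3 exons) had 89 and 7031 counts in heterozygotes and 0 in both homozygous libraries, at least 1088-fold lower than the heterozygous mean. Heterozygous replicate 2 carries that bound, and against heterozygous replicate 1 alone it is at least 42.1-fold. pdx1, a transcription factor gene of pancreas and duodenum, was at 11.6 and 18.4 CPM against 1.48 and 6.83.

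Stromal and endothelial genes fell as a list, with 28 of 32 lower (camera adjusted p = 2.04e-05; adjusted p = 0.732 with an estimated correlation). pecam1, an endothelial adhesion gene, averaged 15.8 ± 2.83 and 4.22 ± 1.79 CPM, 3.78-fold lower (-1.92 ± 0.49, SE), and the collagen gene col1a1a was at 65.9 and 322 against 59.4 and 36.8 CPM. In 12 of the 32 both homozygous libraries lay below both heterozygous ones, and in 0 above. The list took 0.207% of counts in heterozygous replicate 2 and 0.0441% to 0.0562% in the other 3 libraries, and without that library its mean log2 fold change was 0.13 and its adjusted p 0.944, within a range over the alternatives of 2.81e-13 to 0.944. The liver (29 of 31 lower, camera adjusted p = 0.262), erythrocyte (10 of 11 lower, 0.740) and remaining complement lists (19 of 21 lower, 0.595) were not called. Heterozygous replicate 2 was the highest library for each of c8g, c8a, c3a.3, c9, ambp, rbp4, cahz, epb41b, hbaa1 and ba1l. Without it the mean log2 fold changes of these 3 lists were 4.99, 2.71 and 3.68, all called in the opposite direction, while without heterozygous replicate 1 all 3 lists were called lower. Without homozygous replicate 2 the liver list was also called lower (mean -4.43).

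**Figure D4:**
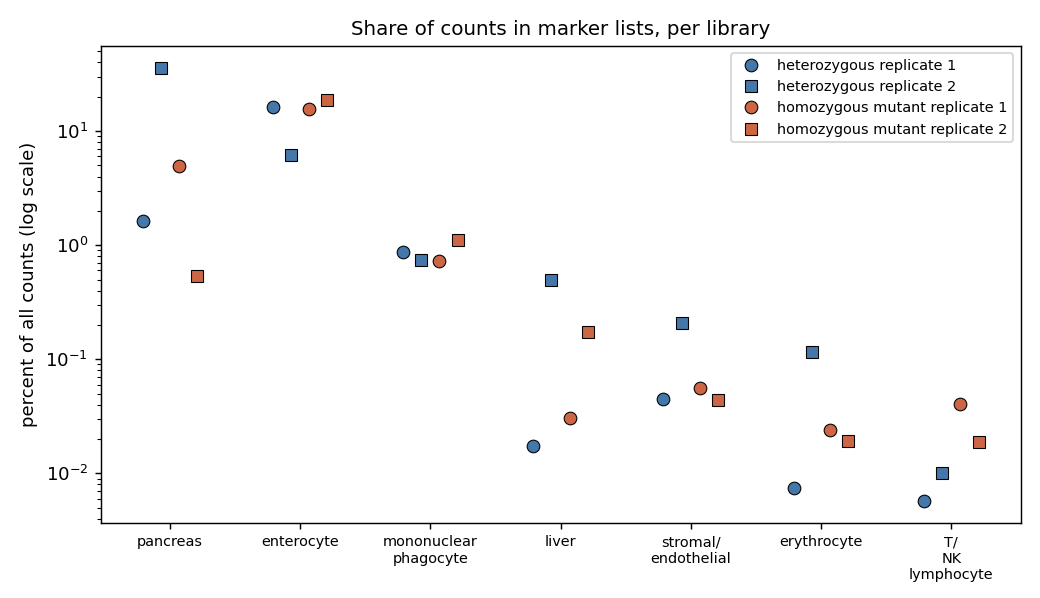
Share of all counts (y axis, percent, log scale) in 7 marker lists (x axis) for the 4 libraries; blue is heterozygous, orange homozygous, circles replicate 1 and squares replicate 2. Heterozygous replicate 2 is highest for pancreas (36.0%), liver, stromal and erythrocyte genes and lowest for enterocyte genes (6.17%).

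Cell cycle genes fell as a list, with 32 of 34 lower and a median log2 fold change of -0.49 (camera adjusted p = 1.13e-05; adjusted p = 0.545 with an estimated correlation). mcm5, a replicative helicase gene, averaged 36.8 ± 0.197 CPM in heterozygotes and 18.1 ± 1.13 in homozygotes, 2.03-fold lower (-1.02 ± 0.33, SE). cdk1, the mitotic kinase gene, averaged 13.3 ± 0.0231 and 6.95 ± 1.48 CPM, 1.92-fold lower (-0.94 ± 0.41). With the preset correlation the cell cycle and interferon calls held without each library in turn. Smooth muscle and enteric neural genes were not called (12 higher and 5 lower, camera adjusted p = 0.610), but each library left out gave a call, lower without replicate 1 of either genotype and higher without replicate 2 of either, with means from -2.24 to 2.24. Lipid and sterol genes were not called (34 higher and 22 lower, camera adjusted p = 0.595) except as higher without heterozygous replicate 1 (0.0337) or homozygous replicate 1 (0.0122; range 0.0122 to 0.943). Within that list pdk4, the gene for a kinase that restrains glucose oxidation, was 5.38-fold higher (2.43 ± 0.68), and srebf1, a lipid synthesis regulator gene, 3.67-fold (1.87 ± 0.59). The genes of sterol and fatty acid synthesis hmgcs1 and acaca were 3.74-fold and 4.10-fold lower (-1.90 ± 0.57 and -2.04 ± 0.64). With each library left out in turn, the smallest changes were 1.45 for pdk4, 0.83 for srebf1, -1.18 for hmgcs1 and -1.10 for acaca.

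Across all genes, edgeR gave 0 calls, with 628 genes at an unadjusted p under 0.05 (354 higher and 274 lower, where 485 would be expected by chance). DESeq2 called 55 genes, 29 higher and 26 lower, and 53 of these had non-overlapping libraries, against 39.2% of all tested genes and 33.3% by chance. The calls were made on these same libraries, so that separation is no separate support for them. Of the 21 lists tested, 11 were called with the preset correlation, 0 with an estimated correlation and 0 with fry. The loss with an estimated correlation does not measure correlation alone. That setting also draws its degrees of freedom from the few libraries, where the preset draws them from the genes. Few lists could pass it here, so its 0 calls neither support nor exclude a shift of a list. In the interferon list the estimate of 0.00988 was near the preset 0.01, yet the unadjusted camera p went from 1.34e-05 to 0.0488. In the 16 tested lists other than the C1q, T and NK, B lymphocyte, interferon and goblet and enteroendocrine lists, 0 genes were called adjusted over the list alone. The common dispersion of 0.243 is a coefficient of variation of 49.3% between fish of one genotype. Without heterozygous replicate 1 edgeR called 45 genes, 44 of them lower, and DESeq2 called 239.

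The study's own list of genes went the same way as the counts. Of the 76 genes in the authors' deposited table, 41 matched, 37 were tested here, and all 37 had the sign of the authors' log2 fold change (27 lower and 10 higher). The table does not name its groups, and its signs are those of homozygous over heterozygous in every one of these genes. The correlation with the authors' deposited table across these genes was r = 0.990, and the median absolute difference was 0.09 on the log2 scale. Of the 37, 0 were called over all genes and 33 adjusted over the list alone, which is not independent evidence because the list was chosen on these samples; DESeq2 called 25 of the 41, and 5 of the 37 had overlapping libraries. The higher genes with the smallest p here were aif1l (6.80-fold, 2.76 ± 0.38, SE), ptgdsa, a prostaglandin D synthase gene (11.7-fold, 3.54 ± 0.57), casp8l1 (10.9-fold, 3.45 ± 0.60), irf1b and ccl19b. The lower ones were ggact.2 (40.8-fold, -5.35 ± 0.61), zgc:101699 (11.4-fold, -3.52 ± 0.41), dio2, the gene for a deiodinase that activates thyroid hormone (9.10-fold, -3.19 ± 0.50), zgc:153284 and tuba8l3. All 10 were called by DESeq2.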

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

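Every alternative here was chosen before the results were seen except the newer quasi-likelihood fit and the DESeq2 counts without libraries, with the block and without pancreas and liver genes. DESeq2 called 55 genes (29 higher, 26 lower) where edgeR called 0. Leaving out 1 library gave 0 to 45 edgeR calls (0 to 1 higher, 0 to 44 lower) and 16 to 239 DESeq2 calls, of which 31 of 239 without heterozygous replicate 1 and 4 of 16 without homozygous replicate 2 were among the 55. A group left with 1 library is assumed to vary like the other group. Of the 45 genes, 4 were in the pancreas list and 0 in the liver list. The other edgeR alternatives, with the newer fit (706 genes at an unadjusted p under 0.05), called 0 genes. The lists called went from 11 to 0 with an estimated correlation and 0 with fry, and to between 9 and 15 of them without 1 library. Without heterozygous replicate 1 the gonad list was tested as well and called, which makes 16. The replicate number as a block left 0 edgeR calls and 37 DESeq2 calls, 27 of them among the 55. No source used here says that the numbers pair the fish. Same-numbered libraries deviated together at r = 0.0643 across genes. That value cannot decide the question, since heterozygous replicate 2 departed from the other libraries in pancreas and other genes. Without pancreas and liver genes DESeq2 called 63. DESeq2's size factors moved the median log2 fold change by -0.001.

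The irf8 value lay between -1.17 and -0.52 under all alternatives. By direction of the test, 9 lists reversed without 1 library, with mean log2 fold changes from lowest to highest of -2.49 to 3.68 (other complement), -0.84 to -0.03 (mononuclear phagocyte list, higher without heterozygous replicate 2 by the test though its mean was -0.0313), -0.47 to 1.81 (inflammatory), -0.77 to 1.15 (antimicrobial), -1.48 to 0.28 (goblet and enteroendocrine), -2.24 to 2.24 (smooth muscle and enteric neural), -2.39 to 2.71 (erythrocyte), -4.43 to 4.99 (liver) and -0.54 to 0.31 (lipid and sterol). The goblet and enteroendocrine list also reversed without a count filter (-1.03), at a mean of at least 1 CPM (-1.29) and with the replicate block (-0.30), and the smooth muscle list without a filter (-0.30) and at 1 CPM (-0.31). The neutrophil call ended with the block (adjusted p = 0.0632) and without pancreas and liver genes (0.0542), and the inflammatory call at 1 CPM (0.0806). The liver list was called without a filter (0.0386) and with the block (0.0491).

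Among named genes, the ranges without 1 library crossed 0 for c8g (-3.28 to 1.01), c8a (-4.98 to 3.04), c3a.3 (-3.10 to 1.75), c9 (-3.98 to 8.20), kita (-0.71 to 0.93), rnasel2 (-7.95 to 8.36), cd81a (-1.23 to 0.79), zgc:194626 (-4.45 to 2.69), hand2 (-2.2 to 1.09), cahz (-3.15 to 1.45), epb41b (-3.19 to 1.80), ba1l (-2.98 to 1.4), hbaa1 (-3.10 to 1.66), zgc:112302 (-6.17 to 0.60), ambp (-3.06 to 0.28) and rbp4 (-2.71 to 0.60). All but kita and rnasel2 turned without heterozygous replicate 2, the highest library for these genes. The extremes of c9 and rnasel2 come from groups at 0 and depend on the prior count. The cause of the other reversals was not tested. At this depth and spread, edgeR recovered 0% of simulated 2-fold changes, so differences of that size were not detectable gene by gene.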

Other observations

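All lists and tests in this part were chosen after the results were seen, except the test of islet genes other than insulin and the comparison of genes near irf8, whose outcome had not been seen. Genes of the circadian clock and its outputs were higher in homozygous guts in 18 of 21 cases, with a median log2 fold change of 1.07 (camera p = 6.94e-08; p = 0.106 with an estimated correlation; fry p = 0.0587). per3 was at 1.02 and 1.09 CPM in heterozygotes and 4.44 and 11.2 in homozygotes, and bhlhe40 at 137 and 140 against 274 and 425. The core activator genes arntl1a (-0.04) and arntl2 (-0.49) and bhlhe41 (-0.52) were the 3 not higher. Other core activator genes were higher, with 0.91 for arntl1b, 1.47 for clocka, 1.07 for clockb and 1.38 for npas2. The median was 1.35 without heterozygous replicate 2 and 1.33 without homozygous replicate 1. Of 19 genes of the fasting response, 12 were higher, with a median log2 fold change of 0.35 (camera p = 0.0258; p = 0.521 with an estimated correlation), 1.41 without heterozygous replicate 2 and 0.15 without homozygous replicate 1. Its members went both ways, with irs2a higher (2.30 ± 0.49, SE) and ucp3 lower (-4.10 ± 0.83). Tests of sampling time and of fed state as reasons for the clock genes were run and are not weighed further: the first asked for p under 0.05 with an estimated correlation and missed it, and the second asked for p under 0.05 with the preset correlation and met it.

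Within 10 Mb of irf8 on chromosome 18, 5 of 114 tested genes (4.39%) had an unadjusted p under 0.05, against 623 of 9586 other genes (6.50%; two-sided Fisher's exact test, p = 0.447).

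Pancreas, stromal and endothelial genes were lower in homozygous guts. Whether 1 heterozygous gut carried extra pancreas and other attached tissue was asked only after its shares of counts had been seen. Without heterozygous replicate 2 the pancreas list had a mean log2 fold change of 0.12 and the stromal and endothelial list an adjusted p of 0.944 (mean 0.13). These values repeat the observation that prompted the question and add no support, so extra tissue and a genotype effect, which was not tested, cannot be told apart. The same library was highest for liver and erythrocyte genes.

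Insulin had 0 counts in homozygous guts, where homozygous replicate 1 held 314069 counts of 24 exocrine genes, more than the 101676 of heterozygous replicate 1, and at the latter's insulin to exocrine ratio 275 insulin counts would be expected, and 43.0 in homozygous replicate 2. This argues against too little pancreas in the homozygous samples, although that ratio, the lower of the 2 heterozygous ones, comes from a single fish. Islets may instead have been unevenly carried over, since 5 islet genes other than ins had a median log2 fold change of -1.52 against heterozygous replicate 1, but none exceeded 9 counts there. Of these, sst1.1 had 5 and 778 counts against 0 and 0 and nkx6.1 and nkx2.2a were lower (-1.88 and -1.52), while insm1b (0.00) and scgn (1.08) were not, so uneven islets and a difference in the insulin cells themselves cannot be told apart.

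Transporter and peptidase genes of the brush border were higher in homozygous guts in 14 of 14 cases (median log2 fold change 1.23; 1.07 without heterozygous replicate 2), while 16 of 18 genes of ileal and lysosome-rich enterocytes, fabp6 among them, were lower (median -0.96; -0.32 without that library). With an estimated correlation neither list was called (camera p = 0.136 and 0.347; fry p = 0.0479 and 0.371). Among the 18 ileal and lysosome-rich genes, lgmn and hexb are also in the mononuclear phagocyte list and tdo2b in the liver list. Whether the fall lies in enterocytes alone was not tested. Dilution of enterocyte transcripts by pancreas in 1 heterozygous gut would move both lists the same way. Their medians lay 2.19 apart, where the combined SD over their genes was 1.06. The comparison of medians replaced a test whose outcome had been seen and which did not decide. In that earlier test the transporter bound of 1 was passed by less than the SD of 0.686. Its ileal bound was set in the wrong direction. Both lists were chosen after transporters had been seen higher and fabp6 lower, and the SD is over genes, not fish. The gap between the medians therefore restates that pattern and excludes nothing. Dilution alone would not give opposite directions, but whether it contributed was not decided. A larger share of anterior gut in the homozygous samples may contribute: 10 lipid-absorbing genes of that region had a median of 0.29 (range -0.27 to 1.11), between what that share predicts and no change, and -0.35 without heterozygous replicate 2, so it cannot be told apart from a genotype effect, which was not tested separately.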
